A study of Mus musculus with 12 samples.

How the data were processed

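RNA was sequenced from peritoneal macrophages, the phagocytes of the abdominal cavity, of C57BL/6 mice. The cells came from wild-type (WT) mice or from mice lacking CD36, a scavenger receptor that binds oxidized lipoproteins and long-chain fatty acids (CD36 KO). They were kept in culture and given either medium alone or oxidized low-density lipoprotein (oxLDL) at 20 µg/ml for 8 h. Each of the 4 groups had 3 libraries, 12 in all, and every library was placed in its group by its title. The labels do not say whether the replicates came from separate animals or cultures, so every p-value measures only the spread between these samples, which may be technical. They also do not say how the peritoneal cells were purified, which part of Cd36 was removed, or where the control mice came from.

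The deposited count table holds whole-number counts per gene for each library, without normalization, and the values sum to different totals in each library. The same table holds RPKM values, which the authors computed from the counts: the library total each RPKM column implies lay 0.0232% to 0.0284% above the summed counts. The deposited result tables hold log2 fold changes and log2 CPM made by the authors from those counts. They also hold the authors' p-values and false discovery rates, together with scores: a dispersion per gene, a likelihood ratio and, per the file headers, a call of higher or lower. Genome build mm10 and FastQC are named in the submitters' processing notes. The aligner, the counting program, the gene annotation and the authors' test program are not given in the sources used here, and neither is whether counting used the strand. Antisense and overlapping genes, near-identical copies and nuclear copies of mitochondrial genes can therefore share reads, and their values are uncertain. Gene identifiers, symbols and coordinates (mm10) are those of the count table. Of its 43346 gene identifiers, 42462 (98.0%) were found in GENCODE M21, an annotation of the same assembly.

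The counts were the input of every test here. The RPKM values and the authors' log2 fold changes were used only for checks, and the authors' false discovery rates only for the counts credited to their deposited tables. Genes with few counts were left out with edgeR's filterByExpr (minimum count 10, minimum total count 15), which kept 16281 genes. Libraries were scaled with TMM factors. One edgeR quasi-likelihood model (edgeR 4.0.16, R 4.3.3) with 1 mean per group was fitted to all 12 libraries, so that the groups share one estimate of the spread. The contrasts were oxLDL against control in WT and in CD36 KO, CD36 KO against WT in each medium, the difference between the oxLDL responses (the interaction), and the oxLDL effect averaged over both genotypes. P-values of each contrast were adjusted by the Benjamini-Hochberg method, and a gene is called changed at an adjusted p under 0.05. Every adjusted p printed for a gene comes from this test unless another tool is named. Fold changes are log2 values with an approximate standard error (SE). It is the absolute log2 fold change divided by the square root of the F statistic of the test. The SEs of single responses need not combine into that of the interaction. Levels are TMM-scaled CPM (counts scaled to library size), given as mean ± SD over 3 libraries. Logarithms of CPM used a prior count of 2.

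The contrasts, tests, filters, naming rule and 27 gene lists were fixed before the data were examined. The lists cover NRF2 targets, LXR targets, SREBP2 targets, PPAR targets and lipid storage, mitochondrial fatty acid oxidation, NF-kB-driven inflammatory mediators, type I interferon-stimulated genes, and glycolysis with HIF1 targets. They also cover the nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, mitochondrial antioxidant and uncoupling genes, the integrated stress and unfolded protein response, scavenger and pattern recognition receptors (without Cd36), lysosome and autophagy genes, and proliferation. Further lists hold genes of alternative activation, of large and of small peritoneal macrophages, and immediate-early genes that can respond to handling. The remaining lists hold markers of other cells of the peritoneum or blood: B cells, T cells, neutrophils, mast cells, eosinophils, dendritic cells, mesothelial cells and fibroblasts, and erythroid cells. Macrophages express some of these markers themselves. A list needed at least 3 tested members for a set test, and the erythroid list had 0 of 5. Sets were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with the p-values adjusted over the lists of a contrast, and again with a correlation estimated from the data. The estimated version treats members that rise and fall together across libraries as less independent, and its p is given where it ended a call. Counts of called members are given over all genes tested and "adjusted over the list alone".

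Genes named in the text follow one rule. Cd36 comes first. Each comparison then names the 6 genes with the largest rise and the 6 with the largest fall among called genes with a mean of at least 5 CPM in the higher group and no overlap between libraries. For the interaction these are the 8 largest in each direction, with no overlap asked. From each list come up to 4 called members with the largest change and up to 2 uncalled members with the highest CPM. Predicted genes, clones without a name and pseudogenes were passed over. Not every gene the rule allows is printed, and the choice among them was made after their values and their behaviour under the alternatives had been seen.

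Summed counts ran from 35257762 to 65135955 per library. At this depth the spread between libraries, not counting, limits the precision of all but the lowest genes. Where a group held 1 to 3 counts of a named gene, the fold is given with its exact 95% counting interval; where it held 0, a floor of 3 counts over the group gives a lower bound. Such intervals and floors cover counting error only. Each test was run on simulated counts with known changes. They were drawn at the depths of these libraries, with the mean and spread of a gene taken alike in all of them. No simulated library stood apart from its group, whereas WT oxLDL replicate 1 did. The shares found and the false calls may therefore differ from those in the real data. Each simulation changed 67 genes by 1.5-fold, 67 by 2-fold and 66 by 4-fold, far fewer than the 5980 called for oxLDL in WT. The Benjamini-Hochberg adjustment is stricter when few genes change, so the shares found may be too low for contrasts with many changes. For oxLDL in WT the edgeR test found 0% of genes changed 1.5-fold, 31.3% of those changed 2-fold and 92.4% of those changed 4-fold (15969 genes). For the interaction the same shares were 0%, 11.9% and 63.6% (15968 genes). False calls made up 3.25% to 7.61% of edgeR's calls over the contrasts and 19.8% to 25.0% of those of DESeq2.

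The alternatives were DESeq2 (1.42.0), RLE and upper-quartile factors, no low-count filter, a stricter filter (1 CPM in at least 3 libraries), a fit of only the groups compared, the replicate number as a block, leaving out each library in turn, and the set test fry. Chosen after seeing the data were limma's voom with a quality weight per library, an edgeR offset that removes each library's trend of expression with gene length, gene lists counted without WT oxLDL replicate 1, and genotype calls counted without the genes of the other-cell lists. No library was left out of the main results. The result of 1 gene is not reported here because the gene is withheld.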

Results

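Expression of 16281 genes was compared in 12 RNA-seq libraries of mouse peritoneal macrophages: WT and CD36 KO cells, each in control medium or with oxLDL at 20 µg/ml for 8 h, with 3 libraries per group. OxLDL is the modified lipoprotein that macrophages take up when they become foam cells, and CD36 is one of its receptors. Summed counts were 39579947 to 44409108 per library in WT control, 40883239 to 65135955 in WT oxLDL, 35257762 to 38237421 in CD36 KO control and 35940504 to 46714685 in CD36 KO oxLDL. The first principal component of the log2 CPM held 55.8% of the variance and the second 23.1%. Within groups, libraries correlated across genes at r = 0.988 to 0.995, except that WT oxLDL replicate 1 reached only 0.952 and 0.953 with the other libraries of its group. That library had the lowest TMM factor (0.729, others 0.838 to 1.18), and Fth1, which encodes the ferritin heavy chain, took 4.52% of its counts. Its mean log2 CPM of long genes exceeded that of short genes by 1.48, against 2.31 to 2.95 in the other libraries. No pair of replicates agreed within sampling noise (lowest chi-square per degree of freedom 3.0), so each library was counted as 1 sample.

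**Figure D1:**
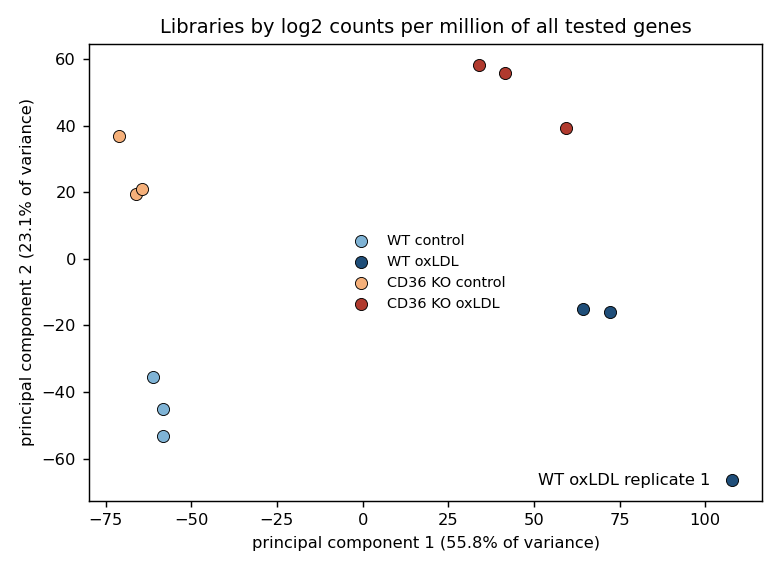
Principal components 1 (x axis, 55.8% of the variance) and 2 (y axis, 23.1%) of the log2 CPM of 16281 genes, with 1 point for each of the 12 libraries coloured by group. WT oxLDL replicate 1, named in the plot, lies away from the other libraries of its group.

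Cd36 (ENSMUSG00000002944, chromosome 5, 17781690 to 17888801, mm10) was measured first as a check of the labels. It stood at 5362 ± 106 CPM in WT control, 3100.5 ± 1048 in WT oxLDL, 481 ± 28.3 in CD36 KO control and 199 ± 7.58 in CD36 KO oxLDL (SD, n = 3), and each of the 6 CD36 KO libraries was below each of the 6 WT libraries. CD36 KO cells held 8.98% of the WT level in control medium and 6.42% under oxLDL. The log2 fold changes were -3.48 ± 0.23 (SE, adjusted p = 1.73e-05) and -3.96 ± 0.23 (adjusted p = 5.41e-06). Counts per gene do not show which exons the remaining reads came from. With oxLDL, Cd36 fell by 0.79 ± 0.21 on the log2 scale in WT (adjusted p = 0.0116, but 0.0873 when only the WT groups were fitted) and by 1.27 ± 0.21 in CD36 KO (log2 fold change -1.27, adjusted p = 0.000818). The difference between these responses did not pass the test (-0.48 ± 0.29, adjusted p = 0.661). WT oxLDL replicate 1 held 1899 CPM of Cd36, against 3578 and 3825 in replicates 2 and 3. The size of the WT fall and of this difference therefore leans on that library.

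**Figure D2:**
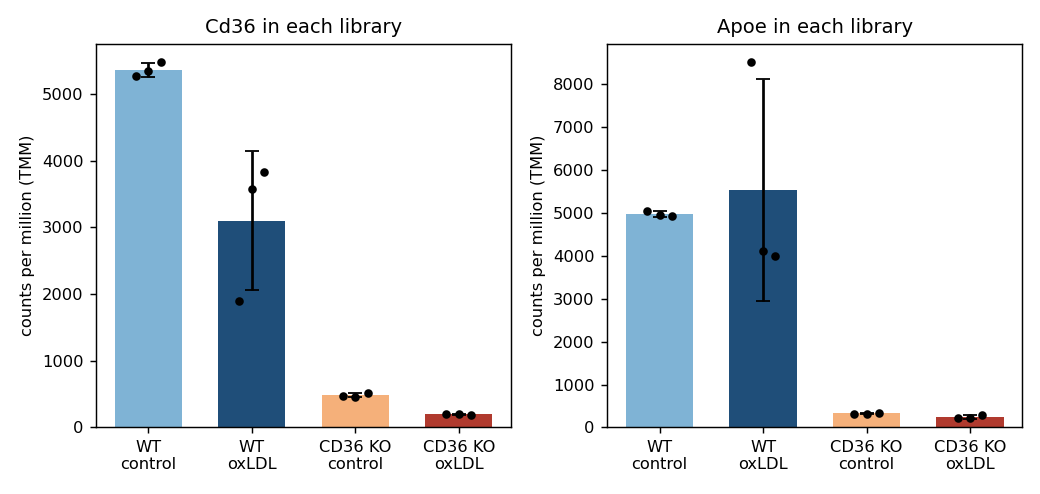
TMM-scaled CPM (y axis) of Cd36 and Apoe in each group (x axis), with bars for the mean of 3 libraries, error bars for 1 SD and points for single libraries. Cd36 averaged 5362 CPM in WT control and 481 in CD36 KO control, and Apoe 4968 and 329.9.

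What WT macrophages did in response to oxLDL was the first comparison. Most of the tested inflammatory mediators rose, Il1b, Cxcl3, Nos2 and Il12b from close to nothing. Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), which encodes the cytokine interleukin-1 beta, went from 1.16 ± 0.825 to 2014 ± 496 CPM (SD, n = 3). The antioxidant gene Hmox1 and the oxLDL receptor gene Olr1 rose too. Pparg, which encodes a lipid-sensing nuclear receptor, and the cholesterol synthesis genes Dhcr7 and Sc5d fell. In all, 5980 of 16281 genes changed, 2946 up and 3034 down.

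Of 23 tested NF-kB-driven mediators, 22 rose and 0 fell in WT, also when adjusted over the list alone, with a median log2 fold change of 4.92. Il1b rose by 10.77 ± 0.65 (SE, adjusted p = 2.29e-07), the neutrophil chemoattractant gene Cxcl3 by 9.79 ± 0.42, Nos2, the inducible nitric oxide synthase, by 9.41 ± 0.83, and Il12b, a subunit of interleukins 12 and 23, by 7.88 ± 0.70. The set passed camera (adjusted p = 7.07e-60, and 0.000703 with an estimated correlation). All 24 tested interferon-stimulated genes rose, over all genes and adjusted over the list alone (camera adjusted p = 1.04e-49, and 0.0106 with an estimated correlation). Their summed level went from 902 ± 91.7 to 16297 ± 919 CPM. Among them, Cxcl10 rose by 7.74 ± 0.46, the ubiquitin-like modifier Isg15 by 6.50 ± 0.36, and Mx1, an antiviral GTPase, by 6.01 ± 0.32 (adjusted p = 9.12e-08). Of 24 NRF2 targets, 18 rose and 0 fell by either adjustment (camera adjusted p = 8.38e-09, and 0.0409 with an estimated correlation). Slc7a11, the cystine importer used for glutathione synthesis, rose by 4.77 ± 0.35 (adjusted p = 1.08e-06), and Hmox1, the heme-degrading enzyme, by 2.61 ± 0.12 (adjusted p = 2.49e-08). The ferritin light chain gene Ftl1 did not pass the test (0.49 ± 0.27, adjusted p = 0.169).

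Cholesterol and lipid genes split in WT. Of 25 SREBP2 targets, a list led by genes of cholesterol synthesis, 0 rose and 13 fell, also adjusted over the list alone (camera adjusted p = 0.000317). With an estimated correlation that call was lost (adjusted p = 0.154). Dhcr7, which catalyses the last step of one branch of the pathway, fell by 2.35 ± 0.12 (log2 fold change -2.35, adjusted p = 6.8e-08), and Sc5d by 1.36 ± 0.12 (-1.36). Of 14 LXR targets 4 rose and 4 fell (camera adjusted p = 0.953), with Nr1h3, which encodes LXR alpha, up by 2.07 ± 0.25. Of 15 PPAR and lipid storage genes 4 rose and 4 fell (camera adjusted p = 0.967). Acsl1, which activates long-chain fatty acids, rose by 4.04 ± 0.22. Pparg fell by 3.10 ± 0.14 (-3.10, adjusted p = 2.64e-08) and the fatty acid binding protein gene Fabp4 by 1.74 ± 0.19 (-1.74). Plin2, which coats lipid droplets, did not pass the test (-0.15 ± 0.16, adjusted p = 0.481). Of 16 fatty acid oxidation genes 1 rose and 5 fell (camera adjusted p = 0.249), among them Hadhb (-1.15 ± 0.13) and Hadh (-1.05 ± 0.11).

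Of 17 scavenger and pattern recognition receptors in WT, 8 rose and 6 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.000202, and 0.0463 with an estimated correlation). The oxLDL receptor gene Olr1 rose by 5.26 ± 0.34, Marco by 4.51 ± 0.16 and Tlr2 by 4.18 ± 0.14. Proliferation genes fell: 16 of 20, and 17 adjusted over the list alone, with 0 up (camera adjusted p = 0.000202). This call was lost with an estimated correlation (adjusted p = 0.509). Bub1, a mitotic checkpoint kinase, fell by 1.60 ± 0.22 (-1.60), and the ribonucleotide reductase gene Rrm2 by 1.36 ± 0.20 (-1.36). Of 20 glycolysis and HIF1 genes 12 rose and 2 fell (15 and 2 adjusted over the list alone; camera adjusted p = 0.153), with the angiogenic factor gene Vegfa down (-2.15 ± 0.18). Both Sod2 (4.78 ± 0.15) and Prdx5 (2.84 ± 0.26) rose among 11 mitochondrial antioxidant genes, of which 2 rose and 2 fell (camera adjusted p = 0.153). Of 44 respiratory chain genes 5 rose over all genes and 0 adjusted over the list alone (camera adjusted p = 0.153). Of 13 mitochondrially encoded mRNAs 0 changed by either adjustment (camera adjusted p = 0.737; the edgeR test without WT oxLDL replicate 1 called 1, lower).

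The remaining lists did not move one way in WT. Of 18 stress response genes 7 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.248), and of 21 lysosome and autophagy genes 4 rose and 6 fell (0.249). In the latter list Sqstm1, an autophagy receptor, rose by 1.88 ± 0.18, and Lipa, the lysosomal acid lipase, fell by 1.32 ± 0.12 (-1.32). Of 12 alternative activation genes 5 rose and 3 fell (camera adjusted p = 0.118), of 17 genes of large peritoneal macrophages 6 rose and 7 fell (0.168), of 9 genes of small ones 3 rose and 2 fell (0.967), and of 11 immediate-early genes 6 rose and 3 fell (0.153). The largest falls among the named genes were those of Angptl7 (-6.49 ± 0.42), the organic anion transporter Slco2b1 (-6.13 ± 0.25) and Rasgrp3 (-6.09 ± 0.24). U90926 was held by 3 counts over the WT control libraries and 6696 over WT oxLDL, a fold of 2390.2 (95% counting interval 818 to 11590.2). Ifng, the gene of interferon gamma, went from 2 to 814 counts, a fold of 436 (121 to 3599).

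Markers of other cells in WT moved in several directions with oxLDL. Summed B cell markers were 33.9 ± 16.1 CPM in control and 31.0 ± 9.82 under oxLDL (SD, n = 3), with 0 of 10 called. Summed neutrophil markers were 131 ± 4.80 and 317 ± 31.8 CPM, with 3 of 8 up and 3 down (camera adjusted p = 0.594). Mast cell markers summed to 2.70 ± 0.372 and 16.9 ± 2.07, where Hdc, the histidine decarboxylase gene, was the 1 of 6 that rose (4.50 ± 0.28; camera adjusted p = 0.133). T cell markers summed to 18.6 ± 1.56 and 5.76 ± 2.19, with 2 of 6 up and 2 down (0.248), the largest fall being that of Cd28 (-5.30 ± 0.28). Of 3 dendritic cell markers 1 rose, Ccr7 (2.78 ± 0.35), and 2 adjusted over the list alone (camera adjusted p = 0.251). Of 10 mesothelial and fibroblast markers 3 fell, and 5 adjusted over the list alone (0.228). Of 3 eosinophil markers 2 fell (camera adjusted p = 0.04, and adjusted p = 0.203 with an estimated correlation), led by Siglecf (-2.67 ± 0.12), and this call was also lost without WT oxLDL replicate 1 (adjusted p = 0.0927). The 0 B cell calls were made by edgeR, which also gave 0 without WT oxLDL replicate 1. None of the 5 erythroid genes had enough counts to be tested.

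With upper-quartile factors the split of oxLDL-responsive genes in WT was 2265 up and 3845 down (37.1% up, against 49.3% with TMM), since that scaling moved the median of all genes by -0.12. The split moved the other way, to 3939 up and 2943 down (57.2% up), with the trend with gene length removed, and to 3576 and 3181 (52.9%) with DESeq2. Without WT oxLDL replicate 1, 8097 genes passed the test. Of the lists above, 18 NRF2 targets then rose and 1 fell, 22 NF-kB mediators and 24 interferon-stimulated genes rose, 21 SREBP2 targets fell and 1 rose, 18 proliferation genes fell and 1 rose, and 9 scavenger receptors rose and 7 fell. With a fit of only the WT groups 3687 genes passed. The scavenger receptor set was lost with voom (adjusted p = 0.276). In the authors' deposited table for this comparison, 3515 of 12764 genes had a false discovery rate under 0.05, and 3479 of those were also called here in the same direction.

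**Figure D3:**
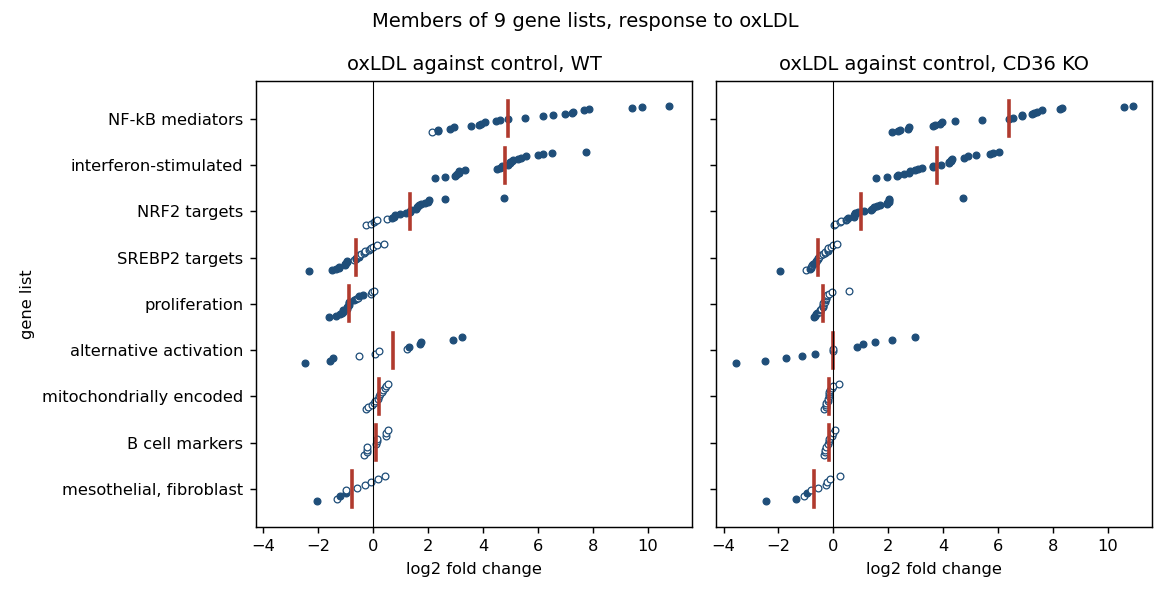
Log2 fold change with oxLDL (x axis) of the members of 9 gene lists (y axis) in WT and in CD36 KO, with 1 point per gene, filled if its adjusted p was under 0.05, and a red bar at the list median. The medians of NF-kB mediators were 4.92 in WT and 6.38 in CD36 KO, and those of interferon-stimulated genes 4.80 and 3.79.

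CD36 KO macrophages were given the same oxLDL, which asks what the response looks like in cells of mice lacking this receptor. Before oxLDL, 1823 genes were called different from WT in these cells, among them Apoe and B cell markers. Differences from the WT response can therefore not be assigned to loss of CD36 alone. CD36 KO macrophages also raised inflammatory, interferon-stimulated and antioxidant genes. Il1b went from 1.41 ± 0.855 to 2153 ± 413 CPM (SD, n = 3), a log2 fold change of 10.57 ± 0.64 (SE, adjusted p = 3.98e-07). Pparg and Dhcr7 fell, as they did in WT. In all, 4454 genes changed, 1893 up and 2561 down. Between the genotypes, whose oxLDL comparisons share no library, 1655 genes rose in both (343 for independent lists), 1973 fell in both (477 for independent lists) and 8 went opposite ways.

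All 23 NF-kB mediators rose in CD36 KO by either adjustment, with a median of 6.38 (camera adjusted p = 3.66e-87, and 0.000366 with an estimated correlation). Cxcl3 rose by 10.91 ± 0.44, Cxcl2 by 8.32 ± 0.17 (adjusted p = 2.65e-10) and Il12b by 8.26 ± 0.69. All 24 interferon-stimulated genes rose by either adjustment, with a median of 3.79 (camera adjusted p = 3.27e-53, and 0.0103 with an estimated correlation). Their sum went from 930.3 ± 203 to 9027 ± 2265 CPM. Isg15 rose by 6.03 ± 0.35 (adjusted p = 2.95e-07) and Ifit1 by 5.82 ± 0.32. Of 24 NRF2 targets 19 rose and 0 fell by either adjustment (camera adjusted p = 3.38e-13, and 0.0103 with an estimated correlation), among them Slc7a11 (4.74 ± 0.35), the peroxiredoxin gene Prdx1 (2.04 ± 0.20) and Hmox1 (2.03 ± 0.12, adjusted p = 2.17e-07). Of 25 SREBP2 targets 10 fell and 0 rose by either adjustment (camera adjusted p = 0.00416), a call lost with an estimated correlation (adjusted p = 0.247). Dhcr7 fell by 1.93 ± 0.12 (-1.93, adjusted p = 3.93e-07), Lss by 0.87 ± 0.13 (-0.87) and Sc5d by 0.82 ± 0.12 (-0.82).

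Of 20 glycolysis and HIF1 genes in CD36 KO 11 rose and 1 fell by either adjustment (camera adjusted p = 0.00262), a call lost with an estimated correlation (adjusted p = 0.247). The glucose transporter gene Slc2a1 rose by 1.13 ± 0.12 and the hexokinase gene Hk2 by 1.12 ± 0.28. Of 17 scavenger receptors 7 rose and 6 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.000489), also lost with an estimated correlation (adjusted p = 0.0836), without the low-count filter (0.058) and with voom (0.478). Olr1 rose by 5.50 ± 0.34, Tlr2 by 4.47 ± 0.14 and Marco by 3.76 ± 0.16. Pparg fell by 2.51 ± 0.14 (-2.51, adjusted p = 1.78e-07) and Fabp4 by 1.98 ± 0.19 (-1.98), while Acsl1 rose, among 15 PPAR and lipid storage genes of which 4 rose and 6 fell (camera adjusted p = 0.845). Of 20 proliferation genes 5 fell and 0 rose (camera adjusted p = 0.166), including Mcm2 (-0.72 ± 0.14). Of 44 respiratory chain genes and of 13 mitochondrially encoded mRNAs edgeR called 0 by either adjustment (camera adjusted p = 0.402 and 0.724). Without WT oxLDL replicate 1 it called 4 of the former up and 2 down, and 1 of the latter down.

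WT oxLDL replicate 1 is not part of this comparison but shares in the common estimate of the spread, the low-count filter and the scaling. Without it, 8315 genes passed. The list counts were then 21 NRF2 targets up, 23 NF-kB mediators and 24 interferon-stimulated genes up, 18 SREBP2 targets down, and 17 glycolysis genes up and 2 down. With each library's trend of expression with gene length removed, the split became 2774 up and 2452 down (53.1% up, against 42.5%), and with upper-quartile factors 1735 and 2826 (38.0%). The authors' deposited table gave 6196 of 13396 genes at a false discovery rate under 0.05, of which 3849 were also called here in the same direction. In all, 3877 genes of that table were called here. Summed neutrophil markers were 70.1 ± 8.08 CPM in control and 160.0 ± 7.04 under oxLDL, and summed eosinophil markers 15.1 ± 0.862 and 4.16 ± 0.294 (SD, n = 3).

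Whether the oxLDL response itself differed between the genotypes was tested with the interaction, in which a positive value means a more positive log2 change in CD36 KO. It passed for 109 of 16281 genes, 38 positive and 71 negative (1680 at an unadjusted p under 0.05). Such a difference cannot be told apart from other differences between the mice or the cell preparations of the genotypes. Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), which encodes the arginine-degrading enzyme arginase 1, rose in WT from 98.1 ± 5.82 to 241 ± 55.8 CPM and fell in CD36 KO from 103 ± 7.36 to 64.1 ± 10.2 (SD, n = 3; interaction -1.97 ± 0.24, adjusted p = 0.00452). F3 (ENSMUSG00000028128, chromosome 3, 121723537 to 121735048), the tissue factor that starts coagulation, rose in CD36 KO from 4.86 ± 0.179 to 28.6 ± 4.1 CPM (2.56 ± 0.22, adjusted p = 6.08e-06). In WT it stood at 6.8 ± 0.391 and 5.96 ± 2.0 (interaction 2.74 ± 0.31, adjusted p = 0.00261). The growth factor gene Hbegf rose in CD36 KO from 6.98 ± 0.266 to 23.0 ± 2.5 CPM and stood at 6.83 ± 0.459 and 5.43 ± 0.66 in WT (interaction 2.06 ± 0.19, adjusted p = 0.00106).

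Nlrp1b (ENSMUSG00000070390, chromosome 11, 71153102 to 71230733), an inflammasome sensor whose sequence varies between mouse strains, fell in WT from 10.3 ± 0.928 to 0.57 ± 0.204 CPM (-4.13 ± 0.22). In CD36 KO it fell from 14.9 ± 0.44 to 9.96 ± 0.934 (-0.58 ± 0.18, adjusted p = 0.0311; interaction 3.55 ± 0.28, adjusted p = 0.000756). Among negative interactions, Ccl12, a monocyte chemoattractant with close paralogs and therefore uncertain, rose from 0.16 ± 0.0111 to 12.1 ± 4.2 CPM in WT and from 0.887 ± 0.0801 to 2.61 ± 1.39 in CD36 KO (-4.66 ± 0.60, adjusted p = 0.00483). The caveolin gene Cav1 rose by 3.98 ± 0.27 in WT and 1.23 ± 0.24 in CD36 KO (-2.76 ± 0.35), and the endothelial lipase gene Lipg by 4.27 ± 0.23 and 1.60 ± 0.24 (-2.67 ± 0.33). Summed mesothelial and fibroblast markers were higher in CD36 KO, at 1934 ± 205 against 765 ± 126 CPM under oxLDL (SD, n = 3). A different mixture of cells could therefore alter interactions, which was not tested. Edn1, the gene of the vasoconstrictor endothelin 1, had an interaction of -3.21 ± 0.41. Fcgr1, the high-affinity IgG receptor, stood at 147 ± 3.2 and 841 ± 268 CPM in WT and at 83.1 ± 7.18 and 98.2 ± 39.5 in CD36 KO (-2.28 ± 0.39, adjusted p = 0.0226). This Fcgr1 call held in 11 of 20 other settings. It was lost with a replicate block (adjusted p = 0.0809) and without any of the WT control or CD36 KO control libraries, CD36 KO oxLDL replicate 1 or CD36 KO oxLDL replicate 2 (0.0518 to 0.0898).

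Of 24 interferon-stimulated genes 0 passed the interaction test over all genes and 8 adjusted over the list alone, all 8 negative (camera adjusted p = 5.64e-09). With an estimated correlation the adjusted p was 0.428. Irf7, a master regulator of interferon genes, had an interaction of -1.07 ± 0.42 (adjusted p = 0.372), and Gbp2, one of a family of similar genes, of -2.05 ± 0.43 (adjusted p = 0.065). Of 20 proliferation genes 0 passed over all genes and 3 adjusted over the list alone, all positive (camera adjusted p = 1.05e-07; adjusted p = 0.428 with an estimated correlation). Of 12 alternative activation genes 2 were negative, and 6 adjusted over the list alone (camera adjusted p = 7.3e-05; adjusted p = 0.428 with an estimated correlation). Without WT oxLDL replicate 1 the list counts over all genes were 9, 3 and 3 in the same directions. The NF-kB list did not pass (camera adjusted p = 0.624). In it the neutrophil chemoattractant gene Cxcl2 had an interaction of 1.05 ± 0.19 (adjusted p = 0.0313). That call held in 7 of 20 other settings, and with any library other than WT oxLDL replicate 1 left out it was lost (adjusted p = 0.0518 to 0.131). In the same list, Il1b (-0.20 ± 0.66, adjusted p = 0.953) and Ccl5 (-0.79 ± 0.51, adjusted p = 0.691) did not pass.

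Over the 7521 genes that changed with oxLDL on average, 5244 (69.7%, exact 95% interval 68.7% to 70.8%, which takes genes as independent) had the larger absolute change in WT. The share was 79.7% among those that rose and 61.7% among those that fell. Those that rose had a median log2 change of 0.96 in WT and 0.66 in CD36 KO. The shares are descriptive, because genes of one library move together. Without WT oxLDL replicate 1 the share was 63.0%, with 74.3% among genes that rose and 53.7% among those that fell. Set tests of the interaction over the genes that rose gave camera p = 2.16e-15, 0.0208 with an estimated correlation and 0.00541 with fry, and without that library 0.0237 with an estimated correlation and 0.000825 with fry. Over the genes that fell they gave camera p = 1.72e-09, 0.0366 with an estimated correlation and 0.148 with fry, and without that library 0.0539 and 0.564. These genes were chosen by the averaged effect in the same libraries, which favours neither genotype only if both responses are equally noisy. WT oxLDL replicate 1 had the lowest voom quality weight (0.0273), so the share and these p-values may lean towards a larger response in WT. In 11 of 100 groupings of the libraries, the real one included, the share lay as far from 50%. In most of the other groupings the larger response went with the label that held WT oxLDL replicate 1. The number of interactions depended on single libraries. It was 1158 without WT oxLDL replicate 1, and 42, 41 and 40 without WT control replicates 1, 2 and 3. It was 48, 52 and 46 without CD36 KO control replicates 1, 2 and 3, and 43 and 44 without CD36 KO oxLDL replicates 1 and 2. It was 535 with DESeq2, and with upper-quartile factors it split into 46 positive and 48 negative (48.9% positive, against 34.9%).

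**Figure D4:**
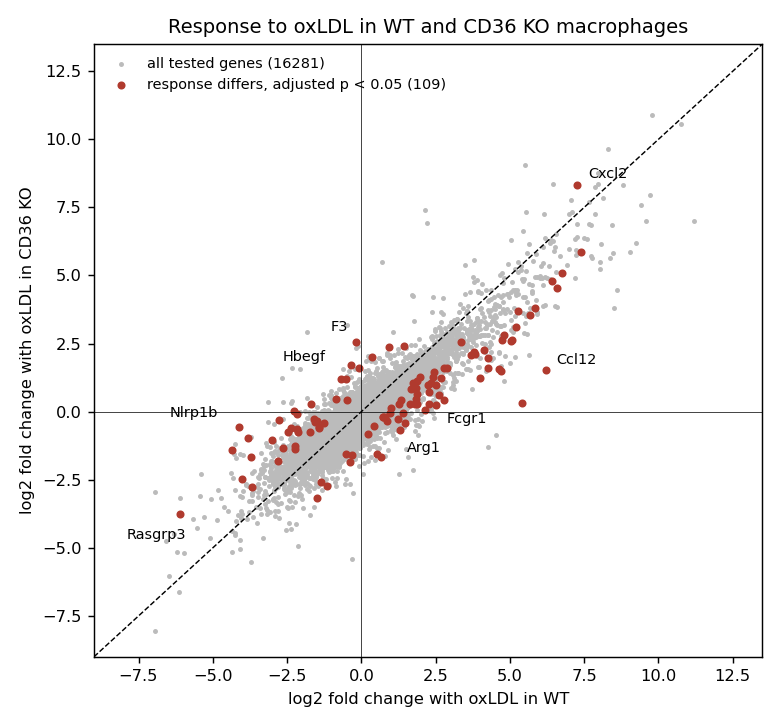
Log2 fold change with oxLDL in WT (x axis) and in CD36 KO (y axis) for all 16281 tested genes in grey, with the 109 genes whose response differed in red and the dashed line marking equal responses. Across genes the values correlated at r = 0.891, and Arg1 lay below the line with an interaction of -1.97.

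CD36 KO and WT cells in control medium were compared to see what differed before any oxLDL was given. Besides Cd36, the deepest falls among the named genes were those of apolipoprotein genes. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), whose protein carries cholesterol out of macrophages, stood at 4968 ± 66.4 CPM in WT and 329.9 ± 14.9 in CD36 KO (SD, n = 3; -3.91 ± 0.29 SE, adjusted p = 2.95e-05). Its neighbour Apoc2 (ENSMUSG00000002992, chromosome 7, 19671579 to 19677941), a cofactor of lipoprotein lipase, stood at 8.97 ± 0.479 and 0.322 ± 0.129 (-4.79 ± 0.39, adjusted p = 6.87e-05). The B cell genes Ighm and Ms4a1 were higher in CD36 KO. In all, 1429 genes were higher and 394 lower.

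All 10 B cell markers were higher in CD36 KO by either adjustment (camera adjusted p = 9.18e-17), a call lost with an estimated correlation (adjusted p = 0.0877). Their sum was 242 ± 144 CPM, against 33.9 ± 16.1 in WT (SD, n = 3). CD36 KO control replicate 2 stood apart at 407 CPM, and the mean without it was 159. Ighm, the constant region of IgM, was higher by 2.78 ± 0.45 (adjusted p = 0.00271) and Ms4a1, which encodes CD20, by 2.55 ± 0.25 (adjusted p = 0.000237). The immunoglobulin genes Ighg3 (6.34 ± 0.81) and Iglv1 (5.51 ± 0.78) were among the largest rises, and such genes share reads with close copies. Mesothelial and fibroblast markers summed to 2409.8 ± 732 CPM, against 944 ± 255, with that library again the highest of its group at 3237. Of 10, 4 were higher and 0 lower, and 6 adjusted over the list alone (camera adjusted p = 0.00299; adjusted p = 0.311 with an estimated correlation). The collagen gene Col1a1 was higher by 1.58 ± 0.22 (adjusted p = 0.00123). Of 6 mast cell markers 3 were higher (4 higher and 1 lower adjusted over the list alone), at summed levels of 7.37 ± 0.715 and 2.70 ± 0.372 CPM (camera adjusted p = 0.00708; adjusted p = 0.311 with an estimated correlation). Dendritic cell markers gave 1 of 3 higher (3 adjusted over the list alone; camera adjusted p = 0.0465; adjusted p = 0.288 with an estimated correlation). Of 6 T cell markers 2 were higher (0.0627). Neutrophil markers were lower, at 70.1 ± 8.08 against 131 ± 4.80 CPM. Of 8, 2 were lower, and 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00299; adjusted p = 0.0877 with an estimated correlation), among them Mmp8 (-1.69 ± 0.14) and Csf3r (-0.69 ± 0.13).

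Mitochondrially encoded mRNAs were higher in CD36 KO: 8 of 13, and 10 adjusted over the list alone, with a median of 0.83 (camera adjusted p = 4e-06). With an estimated correlation the adjusted p was 0.311. These genes have nuclear copies. All genes with a mitochondrial symbol (mt-), not only these mRNAs, took 0.791% to 1.15% of the counts in CD36 KO libraries and 0.470% to 0.658% in WT. The respiratory chain genes encoded in the nucleus were shifted the other way in the set test (camera adjusted p = 0.00557; adjusted p = 0.605 with an estimated correlation; fry adjusted p = 0.479), with 0 of 44 called by edgeR by either adjustment and 4, all lower, without WT oxLDL replicate 1. Nnt, a mitochondrial NADPH-producing enzyme that carries a deletion in the C57BL/6J substrain, was higher by 0.73 ± 0.11 (adjusted p = 0.00217).

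In CD36 KO control cells, of 15 PPAR and lipid storage genes 4 were lower and 1 higher by either adjustment (camera adjusted p = 0.0183; adjusted p = 0.288 with an estimated correlation). Lpl, the secreted lipoprotein lipase, stood at 3639 ± 334 CPM against 7198 ± 181 (SD, n = 3; -0.98 ± 0.16, adjusted p = 0.0027) and Pparg was lower by 0.74 ± 0.13 (-0.74, adjusted p = 0.00419), while Dgat2, an enzyme of triglyceride synthesis, was higher by 1.97 ± 0.26. Of 16 fatty acid oxidation genes 1 was lower, Acadl (-0.64 ± 0.13), and 0 higher (camera adjusted p = 0.00622; adjusted p = 0.398 with an estimated correlation). Apoe and Apoc2 were the 2 of 14 LXR targets that passed the test, both lower. The set passed camera as lower (adjusted p = 0.0157; adjusted p = 0.206 with an estimated correlation) although its median was 0.04, and it did not pass with voom (0.421) or without the low-count filter (0.0752). Abca1, the cholesterol efflux pump, did not pass (-0.17 ± 0.47, adjusted p = 0.909). Of 21 lysosome genes 2 were lower over all genes and 0 adjusted over the list alone (camera adjusted p = 0.00615; adjusted p = 0.317 with an estimated correlation). The abundant lysosomal genes Gpnmb (-0.09 ± 0.12, adjusted p = 0.763) and Ctsd (-0.08 ± 0.16, adjusted p = 0.869) did not pass. NRF2 targets were shifted down in the set test (1 of 24 lower; camera adjusted p = 0.0236; adjusted p = 0.311 with an estimated correlation), as were SREBP2 targets (0 of 25 lower and 1 higher; 0.0312; adjusted p = 0.311 with an estimated correlation; 0.0541 with the stricter filter).

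In control medium, of 24 interferon-stimulated genes 3 were higher and 2 lower (4 and 6 adjusted over the list alone; camera adjusted p = 0.0803), with Ifi44 higher by 3.62 ± 0.36 (adjusted p = 0.00024). Of 23 NF-kB mediators 3 were higher (0.665), with the chemokine gene Cxcl1 higher by 1.47 ± 0.24 (adjusted p = 0.00271). Of 20 proliferation genes 3 were higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0497; adjusted p = 0.605 with an estimated correlation; 0.414 without CD36 KO control replicate 2). Of 12 alternative activation genes 3 were higher and 2 lower (0.267), among them the lectin gene Clec10a (-1.52 ± 0.21). Of 17 genes of large peritoneal macrophages 3 were higher and 1 lower (6 and 3 adjusted over the list alone; camera adjusted p = 0.511), and their sum was 3862 ± 561 CPM in CD36 KO and 2794 ± 178 in WT (SD, n = 3). Of 9 genes of small peritoneal macrophages and monocytes 0 were higher and 1 lower by edgeR (1 and 2 adjusted over the list alone; 0.0791). Their sum was 573 ± 124 and 1003 ± 97.5 CPM. For both sums the libraries of the genotypes did not overlap. Outside the lists, C5ar2, a receptor for complement C5a, was lower (-3.40 ± 0.29, adjusted p = 9.42e-05), and Eno1b, a near copy of Eno1 and therefore uncertain, was higher (5.12 ± 0.19, adjusted p = 2.62e-07).

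The split of genotype differences in control medium depended on the scaling and the test. It was 1300 higher and 509 lower with RLE factors (71.9% higher, against 78.4%). With DESeq2, which changes the test as well as the scaling, it was 1662 and 924 (64.3%). It was 1555 and 1036 (60.0%) with the trend with gene length removed, but 1522 and 332 (82.1%) with upper-quartile factors. The count was 4870 without WT oxLDL replicate 1. That library is again outside this comparison but enters through the common spread, the low-count filter and the scaling. The counts were 928, 853 and 1019 without WT control replicate 2, WT control replicate 3 and CD36 KO control replicate 2. Without WT oxLDL replicate 1, all 10 B cell markers and 11 of 13 mitochondrial mRNAs were higher, 10 NRF2 targets lower and 2 higher, and 9 proliferation genes higher and 1 lower. Fitting only these groups gave 6684 genes. The authors' deposited table held 5494 of 13207 at a false discovery rate under 0.05, of which 1431 were also called here in the same direction. These 1431 were all the genes of that table called here, so the authors' test called more genes.

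**Figure D5:**
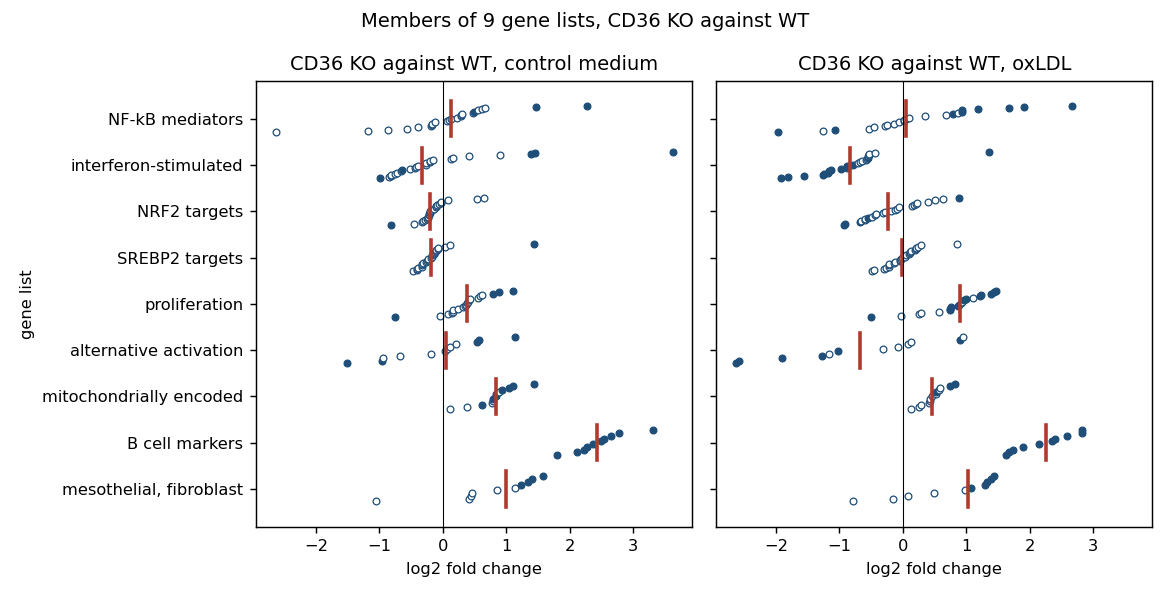
Log2 fold change of CD36 KO against WT (x axis) for the members of 9 gene lists (y axis) in control medium and under oxLDL, with 1 point per gene, filled if its adjusted p was under 0.05, and a red bar at the list median. All 10 B cell markers lie above 0 in both media, and the median of interferon-stimulated genes under oxLDL was -0.83.

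CD36 KO and WT cells were compared last under oxLDL. The interferon-stimulated genes Irf7 and Mx1 were lower in CD36 KO, as were Arg1, Apoe, Apoc2 and the Fc receptor gene Fcgr1. The proliferation genes Top2a and Bub1, the neutrophil chemoattractant gene Cxcl1 and the cytokine gene Il6 were higher. Irf7 stood at 1722 ± 750 CPM in WT and 488 ± 155 in CD36 KO, and Mx1 at 669 ± 18.7 and 177 ± 34.7 (SD, n = 3). In all, 1906 genes were higher and 1606 lower. Between the media, whose genotype comparisons share no library, 1030 genes were higher in both (167 for independent lists), 272 lower in both (38.9 for independent lists) and 27 opposite.

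Of 24 interferon-stimulated genes 13 were lower and 1 higher, and 17 and 1 adjusted over the list alone (camera adjusted p = 2.18e-08). With an estimated correlation the adjusted p was 0.263. Mx1 was lower by 1.92 ± 0.26 (-1.92, adjusted p = 0.000723), Irf7 by 1.82 ± 0.30 (-1.82, adjusted p = 0.002) and Usp18, which limits interferon signalling, by 1.55 ± 0.24 (-1.55). Ifi44 was the 1 that was higher (1.36 ± 0.31, adjusted p = 0.0104). Its neighbouring family member Ifi44l, outside the list, had 0 counts over the WT oxLDL libraries and 3043 over CD36 KO oxLDL, at least 969.6-fold higher against a floor of 3 counts over the group. Such related genes can share reads. Of 23 NF-kB mediators 7 were higher and 2 lower by either adjustment (camera adjusted p = 0.118): Il6 (1.90 ± 0.26, adjusted p = 0.000817) and Cxcl1 (1.67 ± 0.20, adjusted p = 0.000409) were higher, and the T cell chemoattractant gene Ccl5 lower (-1.97 ± 0.37, adjusted p = 0.00371). Il1b (0.10 ± 0.42, adjusted p = 0.896) and its receptor antagonist gene Il1rn (-0.14 ± 0.18, adjusted p = 0.631) did not pass.

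Proliferation genes were higher in CD36 KO under oxLDL: 13 of 20 higher and 1 lower, and 16 and 1 adjusted over the list alone (camera adjusted p = 4.86e-08; adjusted p = 0.258 with an estimated correlation). Top2a, a DNA topoisomerase of dividing cells, was higher by 1.47 ± 0.27 (adjusted p = 0.00353) and Bub1 by 1.38 ± 0.22. All 10 B cell markers were higher here by either adjustment (198 ± 29.3 against 31.0 ± 9.82 CPM summed; camera adjusted p = 5.11e-10; adjusted p = 0.216 with an estimated correlation), led by Ighm (2.82 ± 0.45). Mesothelial and fibroblast markers summed to 1934 ± 205 against 765 ± 126 CPM, with 5 of 10 higher (6 adjusted over the list alone; camera adjusted p = 0.00938; adjusted p = 0.54 with an estimated correlation), among them Col1a1 (1.43 ± 0.22). Of 8 neutrophil markers 3 were lower, and 4 adjusted over the list alone, at 160.0 ± 7.04 against 317 ± 31.8 CPM (camera adjusted p = 0.0183; adjusted p = 0.242 with an estimated correlation). Of 12 alternative activation genes 5 were lower and 1 higher (7 and 1 adjusted over the list alone; camera adjusted p = 0.000888; adjusted p = 0.258 with an estimated correlation; 0.0671 with voom). Arg1 was lower by 1.91 ± 0.18 (-1.91, adjusted p = 7.95e-05), Clec10a by 2.58 ± 0.27 (-2.58) and the lectin gene Mgl2 by 2.62 ± 0.41 (-2.62). Of 17 scavenger and pattern recognition receptors 7 were lower and 2 higher by either adjustment (camera adjusted p = 0.0323; adjusted p = 0.258 with an estimated correlation; 0.0587 with upper-quartile factors), with the Fc receptor genes Fcgr1 (-3.10 ± 0.29, adjusted p = 8.36e-05) and Fcgr2b (-0.93 ± 0.12) lower and the collectin Colec12 higher (1.24 ± 0.18).

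Apoe was lower by 4.51 ± 0.29 under oxLDL (-4.51, adjusted p = 8.96e-06; 5536 ± 2578 against 243 ± 44.7 CPM) and Apoc2 by 7.13 ± 0.49 (-7.13, adjusted p = 1.08e-05). The change in the Apoe difference between media did not pass the test (-0.60 ± 0.36, adjusted p = 0.655). Of 14 LXR targets 6 were lower and 2 higher (6 and 3 adjusted over the list alone; camera adjusted p = 0.00601; adjusted p = 0.216 with an estimated correlation). Abca1 did not pass (-0.36 ± 0.47, adjusted p = 0.625). Of 15 PPAR and lipid storage genes 6 were lower and 1 higher by either adjustment (camera adjusted p = 0.0183; adjusted p = 0.258 with an estimated correlation). Plin2 was lower by 1.19 ± 0.16 (-1.19, adjusted p = 0.000686) and Lpl by 0.95 ± 0.16 (-0.95, adjusted p = 0.00199), while Angptl4, which inhibits lipoprotein lipase, was higher (1.41 ± 0.19). Hmox1 was lower by 0.91 ± 0.11 (-0.91, adjusted p = 0.000419) among 24 NRF2 targets, of which 4 were lower and 1 higher (0.211). Of 16 fatty acid oxidation genes 4 were lower (camera adjusted p = 0.0262; adjusted p = 0.557 with an estimated correlation; 0.149 without WT oxLDL replicate 1). The nuclear respiratory chain list was shifted down (2 of 44 lower, 0 adjusted over the list alone; camera adjusted p = 0.000221; adjusted p = 0.606 with an estimated correlation; 0.282 without WT oxLDL replicate 1). Mitochondrially encoded mRNAs were higher (3 of 13, and 5 adjusted over the list alone; camera adjusted p = 0.0174; adjusted p = 0.557 with an estimated correlation; 0.118 without WT oxLDL replicate 3), and without WT oxLDL replicate 1 all 13 were.

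With upper-quartile factors 2391 genes were higher and 969 lower under oxLDL (71.2% higher, against 54.3%), that scaling moving the median of all genes by 0.12, and with the trend with gene length removed 2052 and 2984 (40.7%). The count was 6205 without WT oxLDL replicate 1, 2068 and 2269 without CD36 KO oxLDL replicates 1 and 2, and 1191 in a fit of only these groups; without WT oxLDL replicate 1, 20 interferon-stimulated genes were lower and 1 higher, and 17 proliferation genes higher and 1 lower. The authors' deposited table gave 1517 of 12793 genes at a false discovery rate under 0.05, of which 1485 were also called here in the same direction.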

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

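The tests of a wrong label, of the oxLDL response without shared control libraries, of LXR activity, of other cells and of the Apoe neighbourhood in both media were chosen after the results they address had been seen. Each gene in this paragraph stood out because its oxLDL response differed between WT and CD36 KO by the edgeR interaction test, and each also passed without WT oxLDL replicate 1. The difference, CD36 KO minus WT on the log2 scale, was positive for Nlrp1b (3.55), Galnt9 (2.93), F3 (2.74), Rasgrp3 (2.35), Nes (2.30), Smpd3 (2.06), Hbegf (2.06), Hmga2 (1.97), Irf4 (1.75), Angptl4 (1.65), Vegfa (1.39) and Cxcl2 (1.05). It was negative for Ccl12 (-4.66), Edn1 (-3.21), Cav1 (-2.76), Lipg (-2.67), Clic5 (-2.47), Timd4 (-2.44), Dgat2 (-2.30), Fcgr1 (-2.28), Arg1 (-1.97), Dusp1 (-0.96) and Il4ra (-0.88). Clic5, Fcgr1, Angptl4, Cxcl2, Vegfa, Il4ra, Irf4 and Dusp1 lost the call with a replicate block and in several fits without a single library. Shares of other cells may differ between the genotypes, as described below. Whether this altered any of these differences was not tested.

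WT oxLDL replicate 1 stood apart from its group, with a lowest correlation of 0.952, and removing each library's trend of expression with gene length raised this only to 0.9645, against 0.989 for other pairs. Its correlation was higher with the mean of the rest of its own group (0.9537) than with that of CD36 KO oxLDL (0.940), WT control (0.901) or CD36 KO control (0.884), but with CD36 KO oxLDL replicate 3 alone it was 0.952, as high as within its group. That CD36 KO library also had a low contrast of long against short genes (2.31) and a low voom weight (0.215), so the closeness does not by itself point to the label, and Cd36 at 1899 CPM, against 511 at most in the CD36 KO libraries, argues against a CD36 KO sample. A weaker response to oxLDL does not account for the distance: its change from WT control had a slope of 1.01 on that of the other WT oxLDL libraries, 0.977 to 1.02 when no WT control library was shared, and on the CD36 KO change its slope was 1.09, against 1.04 and 1.09 for the others. The labels name no biological difference for this library, so none was tested.

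Apoe and Apoc2 were lower in CD36 KO in both media. Lower LXR activity does not account for this in control medium, where the other 12 LXR targets had a median of 0.06 (SEM 0.126) and 0 of them were called lower by edgeR, although 4 were under oxLDL. A segment of another strain's genome around Apoe is open: within 1 Mb, 15 of 43 genes were called in control medium (34.9%, against 11.1% elsewhere, Fisher exact p = 3.64e-05), a share that 2.73% of 8832 windows reached. By the rule written first this value went with the segment, and a requirement that genes move alike in both media was added after the value was seen; it gave 4 of 43 (9.30%, against 7.98%, Fisher exact p = 0.775), and oxLDL alone 13 of 43 (p = 0.192). Loss of CD36 itself is open too, because the groups hold only 1 CD36-deficient line, and an altered Apoe allele in that line was not tested.

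B cell markers and mesothelial or fibroblast markers were higher in CD36 KO. A lower share of macrophages that raises other cell types alike would keep the B cell to mesothelial ratio constant, if macrophages express neither set. The log2 ratio of the sums was higher by 1.44 in CD36 KO control (-3.43 ± 0.381, against -4.87 ± 0.283, SD, n = 3). Macrophages express some of the listed markers, so the changed ratio cannot decide, and a lower macrophage share stays open. Different shares of particular cells are open too. As ratios of geometric means, summed B cell markers were 6.87-fold and mesothelial markers 2.54-fold higher in CD36 KO control. Without CD36 KO control replicate 2, the highest library of its group for both, B cell markers were 5.01-fold higher and the log2 ratio differed by 1.22. Leaving out the genes of the cell-type lists left 1799 genotype differences in control medium and 3485 under oxLDL, but other genes of such cells stay among them.

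Genes called in both genotype comparisons were not clearly gathered within 10 Mb of Cd36 (9 of 83, 10.8%, against 7.98%; Fisher exact p = 0.31). Pseudogenes made up 3.30% of the genes higher in CD36 KO in both media and 4.83% of those higher with oxLDL (Fisher exact p = 0.0613). Both shares were below the 8.60% among all tested genes, and the share among genes lower in CD36 KO in both media was 1.84%.

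Splits of the libraries into other groups were fitted to count how often a result as large arises. The other splits mix libraries from groups that differ, which widens the spread within each new group, and some carry part of the real effects, so they do not show chance alone. For the interaction 1 of 100 splits, the real one, reached 109 genes, with 60 the highest other count. For the averaged oxLDL effect it was 1 of 100, with 1647 the highest other count against 7521. For the share of genes with the larger response in WT (69.7%) chance is not excluded by the splits, since 11 of 100, the real one included, lay as far from 50% (furthest other 27.0%). In most other splits the larger response went with the label that held WT oxLDL replicate 1, so they cannot separate genotype from that library. The set tests over the genes that rose passed with an estimated correlation (camera p = 0.0208) and with fry (p = 0.00541), so these kinds of test differ, and for the genes that fell fry did not pass (p = 0.148). The set tests do not settle the question, because genes chosen by the averaged effect can lean towards WT if its response is noisier. For oxLDL in WT, oxLDL in CD36 KO and the genotypes in either medium only 10 splits exist; the real one alone (1 of 10) reached its count, with 0 genes in the others, but 10 splits cannot give a share under 0.05.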

How the results depend on the processing

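The voom fit with library quality weights, the removal of the gene length trend and the list counts without WT oxLDL replicate 1 were added after the data had been seen. Genes that did not pass a test were chosen for printing after their values under the other settings were known. Small differences of other genes that did not pass, such as mt-Co1, Lpl, Cd68 and Srebf2, changed sign under some settings. For named genes that passed, 7136 results kept their side of the threshold, 632 lost it and 0 reversed. These genes were picked for large changes and the alternatives reuse most of the same libraries. That 0 reversed was therefore nearly fixed by the choice, and the results are not independent. For lists that passed the figures were 783, 97 and 0. For the printed genes that did not pass, 267 results stayed so, 17 passed under another setting and 4 changed sign.

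Genes changed by oxLDL in WT numbered 5980, 3687 with only the groups compared and 10228 with voom. In CD36 KO they numbered 4454, 8347 with voom and 3397 to 8315 with single libraries left out. Differing responses numbered 109, 535 with DESeq2, 2524 with voom, 228 with the length trend removed and 40 to 1158 with single libraries left out. Genotype differences in control medium numbered 1823, 6684 with only the groups compared, 7233 with voom and 853 to 4870 with single libraries left out. Under oxLDL they numbered 3512, 1191 with only the groups compared, 7947 with voom and 2068 to 6205 with single libraries left out. The causes were not tested. Fits of only the groups compared hold fewer libraries, but in control medium such a fit raised the count from 1823 to 6684. That fit also leaves WT oxLDL replicate 1 out of the common spread, and leaving out that library alone gave 4870. The share with the larger response in WT was 71.0% with DESeq2, 70.8% with RLE, 71.1% with upper-quartile factors, 66.0% with voom, and 63.0% to 74.7% with single libraries left out.

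With the replicate number as a block the counts were 5426, 4073, 44, 1521 and 2947 in the order above. No pairing by number was visible: of 18 same-number pairs 2 correlated above 0.1 (-0.399 to 0.357), and 0 libraries correlated best with their own number in every other group. These are deviations from means of 3 libraries, and under oxLDL single libraries dominate them. WT oxLDL replicate 1 and CD36 KO oxLDL replicate 3 reached r = 0.538, so a shared day or animal could be hidden.

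Of the gene lists, 7 passed for oxLDL in WT (4 with an estimated correlation, 18 with fry) and 6 in CD36 KO (3 and 20). For the interaction 3 passed, 5 with upper-quartile factors, 6 without the low-count filter, 7 with voom, 0 with an estimated correlation, 0 with fry, and 3 to 7 with single libraries left out. Of 14 that passed for the genotypes in control medium and 12 under oxLDL, 0 did with an estimated correlation. The NRF2, NF-kB and interferon lists passed for oxLDL in both genotypes in every setting in which lists were tested. Lists were not tested with DESeq2 or in fits of only the groups compared.

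Il1b between genotypes under oxLDL was -0.0816 without WT oxLDL replicate 2 and -0.07 without CD36 KO oxLDL replicate 3, over a range of -0.0816 to 0.257. Its interaction was 0.20 without WT control replicate 1 and 0.43 without CD36 KO control replicate 3, over a range of -0.92 to 0.43. The causes were not tested.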

Other observations

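Ddit4, a stress-induced inhibitor of mTOR signalling, was higher in CD36 KO in both media (0.93 ± 0.18 SE in control medium, edgeR adjusted p = 0.00759; 1.08 ± 0.18 under oxLDL, adjusted p = 0.00199). Among immediate-early genes, whose levels also depend on how cells are handled, the results under oxLDL were mixed, with 2 of 11 higher in CD36 KO and 3 lower (camera adjusted p = 0.295). Of 9 genes of small peritoneal macrophages and monocytes 6 were lower in CD36 KO under oxLDL and 2 higher (camera adjusted p = 0.211), at summed levels of 734 ± 304 against 2146 ± 1095 CPM (SD, n = 3), with WT oxLDL replicate 1 at 3409 and the other libraries of its group at 1487 and 1541.

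Genes higher in CD36 KO in both media were weakly expressed, at a median of 2.65 CPM, against 38.7 CPM for those lower in both and 12.2 CPM for all tested genes.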
